A study of Homo sapiens with 24 samples.

How the data were processed

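The series measured transcripts in DU145, an established human prostate cancer cell line, on 24 Illumina BeadChip arrays of 47323 probes; the design text of the series names another array maker, while the labelling kit and the probe identifiers are those of Illumina. Per the labels, cells were grown in DMEM with 10% FBS, RNA was extracted with Trizol, and labelled with biotin. In 12 arrays total RNA came from cells transfected with a control mimic (NC1 or NC2) or a miR-638 mimic, 4 arrays per group. In the other 12, RNA was recovered with biotinylated NC1, NC2, miR-638 or miR-17, 3 arrays per group. The labels do not say whether replicates were separate cultures, so the p-values measure the spread between these samples, which may be technical.

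The deposited signal table holds a background-subtracted intensity per probe on a linear scale, not normalized between arrays, and a detection p-value for each signal; the authors' software is not stated. The authors' value table is on a log2 scale, floored at 4 (16 on the linear scale), by a method not stated; its column for NC1 mimic replicate 1 equals the log2 of the deposited intensity with that floor. The 6 columns named NC1 and NC2 pulldown are exchanged between these tables. Every control pulldown value here follows the names in the signal table. The mean of both controls does not depend on this.

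The signals were corrected for background and normalized within each experiment with neqc (limma 3.58.1, R 4.3.3), with the background estimated from the deposited detection p-value, an offset of 16, quantile normalization and log2 values. Probes with a detection p under 0.05 on at least 4 mimic arrays or at least 3 pulldown arrays were tested, 22469 and 23742 probes. The platform annotation gives 30113 probes 1 symbol and 8 several, and does not list 17202; 5447 and 6075 probes past the filters had no single name. Symbols were checked through the gene identifiers, and 0 changed. The probe of highest mean stood for its gene, which left 12646 genes in the mimic experiment and 13101 in the pulldown. No probe carries the name FTH1.

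Detected probes numbered 20613 to 22282 per mimic array and 20962 to 22610 per pulldown array. The arrays' number limits the precision. Group means were fitted with limma and moderated with a trend of the variance, tests were two-sided, and a gene counted as changed at a Benjamini-Hochberg adjusted p under 0.05. Each microRNA group was set against the mean of both control groups, the controls against each other, and the pulldowns against each other. Gene lists, 25 in number, were fixed before the data were examined, as were the comparisons and the rule for naming genes. They were tested with camera at a preset correlation of 0.01, adjusted over 72 tests in the 3 main comparisons, and again with an estimated correlation. The overlap of pulldown and mimic genes was tested with Fisher's exact test, two-sided, which takes genes as independent draws. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.

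The mimic arrays fell into replicates 1 and 2 against replicates 3 and 4: residuals of arrays of the same number correlated at 0.68 to 0.77 between groups. The main mimic fit holds no term for these pairs, so its SEs and p-values include the shift between them. So does the correlation estimated for camera in the mimic lists. The pulldown arrays of the same number correlated at -0.33 to 0.56, and those of different numbers at -0.515 to 0.40. Between the control pulldowns the arrays of the same number correlated at 0.12, 0.56 and 0.42, and those numbered 2 stood apart from the others in both, so a pairing of the controls is not excluded. Counts with replicate number as a block are given beside the counts of every comparison and the mimic lists, and values within each pair of mimic replicates for the mimic counts and some of the genes. Leaving out 1 mimic array unbalances the pairs of mimic replicates, so a call lost that way need not rest on that array alone.

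Genes were named by a rule: in each main comparison the 10 largest increases and the 10 largest decreases among genes past the test whose treated arrays all lay above, or all below, every control array; the first 3 each way in the other comparisons; FTH1, FTL and every probed FTH1 pseudogene; up to 4 members of smallest p from each list with members past the test, and up to 2, as values, from a list with none; and the 10 largest of the genes enriched with miR-638 and lower after the mimic. Where an array of the dimmer side was not detected, the difference is a bound, with each array of that side at the higher of its value and the lowest detected signal. Placeholder names were counted and not named: 5 changed genes after the miR-638 mimic, 14 in the miR-638 pulldown, 25 in the miR-17 pulldown, 13 between these pulldowns, 16 between the control mimics and 9 between the control pulldowns.

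Alternatives tried were quantile normalization with no background correction, median scaling, normalization over all 24 arrays, the authors' values, no detection filter, a detection p under 0.01, every detected probe, no variance trend, array weights, the replicate block, each array left out in turn, either control alone, only the groups of a comparison, other definitions of an enriched gene, an estimated camera correlation and split controls. Chosen after seeing the data were a batch term, either pair of mimic replicates alone, leaving out both control pulldown arrays numbered 2, the authors' values with the control columns exchanged, and calls past the test against each control. Tested on simulated data made from these arrays, limma recovered 34 of 100 genes changed by 0.5 log2 and 92 of 100 changed by 1 in the mimic experiment with 0 false calls (77, 99 and 9 with the replicate block), and 38, 91 and 7 in the pulldown. Planned tests of microRNA seed sites were not run, since no transcript sequences were used here.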

Results

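Transcripts were measured in DU145 prostate cancer cells to ask which RNAs the microRNA miR-638 binds and which change when it is raised, in a study of FTH1, the heavy chain of the iron store ferritin, and its pseudogenes. Total RNA was measured after transfection of a miR-638 mimic or of the control mimics NC1 and NC2 (4 arrays each). RNA recovered by pulldown with biotinylated miR-638, miR-17, NC1 or NC2 was measured too (3 arrays each). Mean signal per array ran from 300.0 to 463 in the mimic experiment and from 428 to 629 in the pulldown, where the NC2 arrays spread most (529 ± 91.1 SD, n = 3). Between 43.6% and 47.1% of the probes were detected on a mimic array and between 44.3% and 47.8% on a pulldown array.

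**Figure D1:**
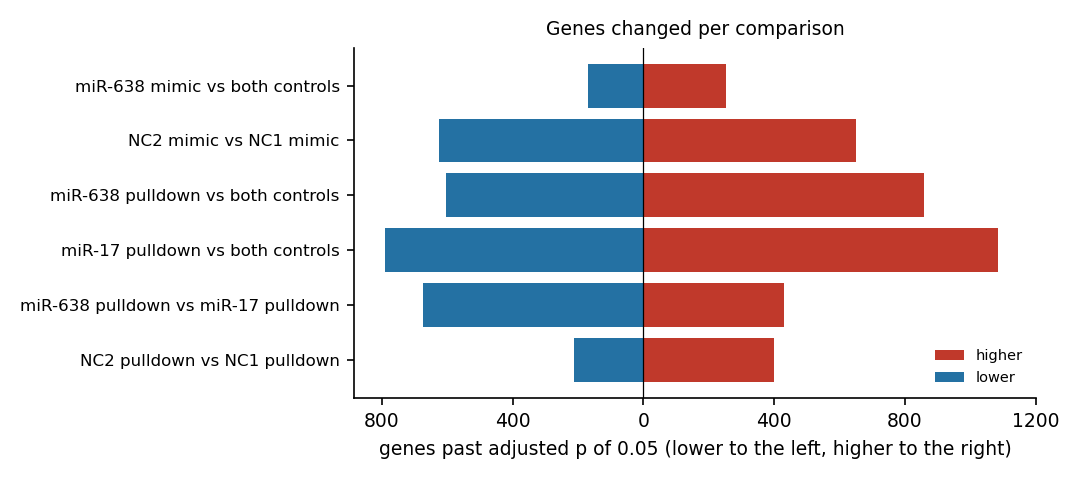
Number of genes past an adjusted p of 0.05 in each comparison, higher to the right and lower to the left of 0. The control mimics differed in 1275 genes and the miR-638 mimic differed from both controls in 422.

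The first comparison, of the miR-638 mimic with both control mimics, asks which transcripts changed when miR-638 was raised. Among the genes of largest increase, TMEM106B, a lysosomal membrane protein, rose by 1.20 (log2, SE 0.15, n = 4 against 8, adjusted p = 0.00156), CANX, the chaperone calnexin of the endoplasmic reticulum, by 1.14 (SE 0.08, adjusted p = 4.53e-05), and MLEC, a lectin of the same compartment, by 0.96 (SE 0.08). PIGS, which helps attach GPI anchors, rose by 0.98 (SE 0.12). CCN2, a secreted matrix protein, rose by 1.02 (SE 0.17, adjusted p = 0.0072). The mitochondrial carrier SLC25A23 fell by 1.66 (SE 0.14, adjusted p = 1.25e-04), and the channel protein PANX2 fell by 1.49 (SE 0.15). RTL8C, a gene derived from a retrotransposon, fell by 1.28 (SE 0.18), the tyrosine kinase ABL1 fell by 1.10 (SE 0.12) and the reductase CYB5R3 fell by 1.03 (SE 0.08). In all, 253 genes rose and 169 fell of 12646, 8 and 11 of them by at least 2-fold in the fitted values.

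The other genes of largest increase were the lactosylceramide synthase B4GALT6 (0.96), the synaptotagmin SYT11 (0.92) and WDFY1 (0.91). PALM3 and the vesicle protein SYNGR3 were also higher, but not well above background on several control arrays (1 and 4 of 8 detected, against 4 of 4 with miR-638), so their increase is given as a bound, at least 1.70-fold and 1.68-fold. The others of largest decrease were FAM222B, -1.07, the lipid kinase PIP5K1C, -1.06, the autophagy regulator TP53INP2, -1.05, and the receptor LRP3, -1.03. Against NC1 alone WDFY1 differed by 0.23 (adjusted p = 0.31) and CCN2 by 0.80 (adjusted p = 0.0567), and against NC2 alone B4GALT6 differed by 0.43 (adjusted p = 0.0588). SYNGR3 had an adjusted p of 0.116 with quantile normalization only. PALM3 had an adjusted p of 0.0135, of 0.0544 with median scaling and of 0.0575 and 0.0581 without miR-638 mimic replicate 1 or 2. LRP3 had an adjusted p of 0.0519, 0.0542 and 0.0502 without NC1 mimic replicate 3, NC1 mimic replicate 4 or NC2 mimic replicate 3. It was 0.113 and 0.0939 without miR-638 mimic replicate 1 or 2. The probes of ABL1 ran from -1.10 to -0.18.

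The decreases were larger in replicates 1 and 2 than in 3 and 4 for several of these genes: SLC25A23 by -2.11 and -1.23, PANX2 by -1.84 and -1.16, RTL8C by -1.82 and -0.76, ABL1 by -1.43 and -0.77. CANX rose by 1.29 and 0.99 and TMEM106B by 1.29 and 1.11. Of the 418 genes called that were also tested within both pairs, 418 had 1 sign in both. They were called on these same arrays, which favours a shared sign, so this is no separate replication. With replicate number as a block, 2432 genes passed, the 422 among them, and 2316 and 858 passed within replicates 1 and 2 and within 3 and 4. Without miR-638 mimic replicate 1, 2 or 4 the count for miR-638 mimic against both controls was 174, 162 and 271. Both the comparison with NC1 and that with NC2 passed, in 1 direction, for 94 genes (34 higher and 60 lower), while 356 passed against NC1 alone and 871 against NC2 alone. Over all genes tested, the 4 treated arrays lay outside all 8 control arrays in 313 (2.48%, against 0.404% for exchangeable arrays). The shift between the pairs of replicates makes the arrays not exchangeable, so 0.404% is no fair reference.

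The only FTH1 pseudogene named among the tested probes, FTH1P3 (probe ILMN_2173835), fell after the miR-638 mimic by 1.17 (SE 0.25, n = 4 against 8, adjusted p = 0.0212), which is 2.26-fold lower. Its level was 11.76 ± 0.25 (log2, SD, n = 4) with NC1, 11.77 ± 0.10 with NC2 and 10.59 ± 0.75 with miR-638. The fall was -1.70 (SE 0.08) within replicates 1 and 2 and -0.64 (SE 0.07) within 3 and 4, and these differed by 1.04 (SE 0.10, adjusted p = 2.48e-06). With the replicate block the adjusted p was 1.72e-06. It was -0.94 (adjusted p = 0.0829) without miR-638 mimic replicate 1, -0.97 (adjusted p = 0.0879) without replicate 2 and -1.18 (adjusted p = 0.0609) with the authors' values. The fits without 1 array hold unequal numbers from the pairs of replicates, so the shift between these pairs enters them. FTL, the ferritin light chain, differed by -0.21 (SE 0.16, adjusted p = 0.649). It differed by -0.39 (adjusted p = 2.84e-04) within replicates 1 and 2 and by -0.03 within 3 and 4. With the replicate block its adjusted p was 0.0272. FTH1 itself was not analysed here, and signal from FTH1 RNA on the pseudogene's probe cannot be excluded. Whether probes with no gene name read other FTH1 pseudogenes was not tested.

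**Figure D2:**
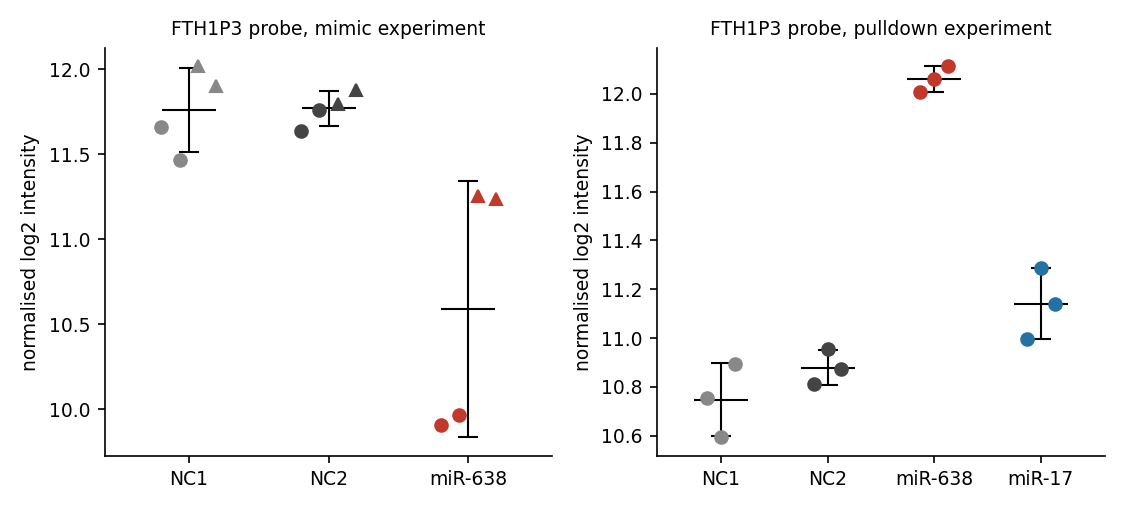
Normalized log2 intensity of the FTH1P3 probe on each array (circles, mimic replicates 1 and 2 and all pulldown arrays; triangles, mimic replicates 3 and 4), with the mean and SD of each group; the axes do not start at 0 and differ between the panels. The 4 miR-638 mimic arrays lie at 9.91, 9.97, 11.25 and 11.23, below the control arrays, and the miR-638 pulldown arrays lie above all others.

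Genes of mitosis were higher after the mimic: 3 of 44 measured members rose, 0 fell and 41 did not pass (7 higher and 1 lower adjusted over the list alone; 12 and 1 with the replicate block). Their median was 0.09 (camera adjusted p = 0.00149; adjusted p = 0.141 with an estimated correlation). CCNA2, the cyclin of S phase and G2, rose by 0.74 (SE 0.07) and TOP2A, the topoisomerase of dividing cells, by 0.66 (SE 0.08). This was a difference from NC2: against NC1 alone the list had a median of 0.02 (adjusted p = 0.956), CCNA2 differed by 0.05 and TOP2A by 0.19. Within replicates 3 and 4 the list's adjusted p was 0.0913. The miR-638 reported targets had 1 of 9 members lower, TP53INP2, 0 higher and 8 not past (5 lower and 1 higher adjusted over the list alone, and also with the replicate block). Their median was -0.21 (adjusted p = 0.0444; adjusted p = 0.376 with an estimated correlation; 0.0799 with the replicate block). Histone genes had 1 of 29 lower and 0 higher, adjusted over the list alone too (10 lower and 2 higher with the replicate block). Their median was -0.15 (adjusted p = 0.0421; adjusted p = 0.376 with an estimated correlation; 0.0753 with the replicate block). The calls of the targets and the histones were lost without NC1 mimic replicate 3 (0.0966 and 0.0864) or 4 (0.0509 and 0.0733). They were also lost without NC2 mimic replicate 4 (0.0751 for both), and without miR-638 mimic replicate 1 (0.0969 and 0.146) or 2 (0.135 and 0.0836). That of the targets was also lost without NC2 mimic replicate 3 (0.0592) and that of the histones without miR-638 mimic replicate 4 (0.0781).

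Among the other lists few members passed, and more did in the blocked fit, whose counts higher and lower are given for each. FECH, which inserts iron into haem, rose by 0.50 in the iron list (1 higher, 0 lower of 27; 1 and 2 adjusted over the list alone; 2 and 7 blocked), but differed by -0.01 against NC1 alone. SRXN1, an antioxidant reductase, was lower by -0.34 (SE 0.05) among NRF2 genes (0 higher, 1 lower of 26; the same counts adjusted over the list alone; 2 and 7 blocked). NDUFB5 of complex I rose by 0.55 in the respiratory list (1 higher, 0 lower of 53, also adjusted over the list alone; 1 and 2 blocked), and differed by 0.15 against NC2 alone (adjusted p = 0.385). Immediate early genes had 2 of 25 higher, CCN2 among them, and 0 lower (3 and 1 adjusted over the list alone; 5 and 1 blocked), with a median of -0.05 and a mean of 0.06. TP53INP1 rose by 0.68 in the lists of reported miR-17 targets (2 higher, 0 lower of 45; 3 and 0 adjusted over the list alone; 7 and 7 blocked) and of p53 targets (1 and 1 of 25, also adjusted over the list alone; 5 and 4 blocked), but differed by 0.14 against NC1 alone. The S phase list had 1 higher and 0 lower of 42 (3 and 0 adjusted over the list alone; 6 and 1 blocked). The microRNA machinery had 1 and 1 of 16 (1 and 2; 1 and 3 blocked), and the unfolded protein list 1 and 0 of 27 (1 and 0; 3 and 3 blocked). Without the block no member passed limma's test in the lists of interferon-stimulated genes (0 of 42; 0 at an unadjusted p under 0.05), NF-kB genes (0 of 18; 3), apoptosis (0 of 29; 4) and growth and invasion (0 of 28; 6). The same held for epithelial and mesenchymal genes (0 of 26; 4), hypoxia (0 of 31; 6), cholesterol synthesis (0 of 28; 2), ribosomal proteins (0 of 64; 6) and splicing factors (0 of 29; 3). Adjusted over the list alone, 1 gene of the NF-kB list was higher and none in the others. In the blocked fit members did pass: 4 higher and 0 lower of the interferon-stimulated genes, 3 and 2 of the NF-kB list, 5 and 1 of apoptosis and 6 and 3 of growth and invasion. They were 5 and 1 of the epithelial and mesenchymal genes, 8 and 3 of hypoxia, 2 and 5 of cholesterol synthesis, 4 and 1 of the ribosomal proteins and 2 and 2 of the splicing factors. The markers of luminal prostate, blood and fibroblasts had 0 of 3, 0 of 8 and 0 of 4 changed by limma (0 unadjusted), and 0, 3 and 0 in the blocked fit, all 3 higher. TAGLN, a smooth muscle actin binding protein, differed by 1.29 (SE 0.46, adjusted p = 0.182; 2.05e-10 with the replicate block). This was more than for any gene named among the largest increases. The difference was 1.51 within replicates 1 and 2 and 1.09 within 3 and 4. The cytokine IL11, detected on 2 of 8 control arrays, was at least 1.25-fold higher (adjusted p = 0.0535; 0.00948 blocked) and RPS28 differed by -0.19 (adjusted p = 0.074; 0.00934 blocked).

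NC2 mimic against NC1 mimic was compared to measure the background between non-targeting sequences. The control mimics differed in 1275 genes, 649 higher and 626 lower with NC2, 46 and 60 by at least 2-fold. MNAT1, an assembly factor of the CDK-activating kinase, was higher with NC2 by 1.82 (SE 0.16, n = 4 against 4, adjusted p = 3.17e-05), PIGN, an enzyme of GPI anchor synthesis, by 1.52 (SE 0.09) and AMMECR1 by 1.52 (SE 0.26). GALNT1, which starts O-glycosylation, was lower by -2.25 (SE 0.11, adjusted p = 6.41e-07), the pseudokinase STRADB by -1.70 (SE 0.10) and the glyoxalase GLO1 by -1.67 (SE 0.09). FTH1P3 differed by 0.01 (SE 0.28, adjusted p = 0.991). Over all genes tested, the NC2 and NC1 arrays did not overlap in 2058 (16.3%, against 2.86% for exchangeable arrays). For the same reason as above, 2.86% is no fair reference. With the replicate block 4164 genes passed, the 1275 among them, and 3626 and 2176 passed within replicates 1 and 2 and within 3 and 4. Of 1255 called genes, 1254 had 1 sign in both pairs, which calling them on the same arrays favours. Without NC1 mimic replicate 1 the count was 801, and without NC2 mimic replicate 1 it was 813.

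The miR-638 pulldown was set against both control pulldowns to ask which RNAs were enriched with miR-638. The cells were not measured before the pulldown, so enrichment by itself does not show binding. FTH1P3 was enriched by 1.25 (log2, SE 0.08, n = 3 against 6, adjusted p = 7.27e-07). Its level was 10.75 ± 0.15 (SD, n = 3) with NC1, 10.88 ± 0.07 with NC2 and 12.06 ± 0.05 with miR-638. RTL8C and LDOC1, both derived from retrotransposon Gag genes, were enriched by 1.73 (SE 0.09, adjusted p = 9.7e-08) and 1.44 (SE 0.09, adjusted p = 4.17e-07). The lysosomal protease CTSZ was enriched by 1.48 (SE 0.17), the imprinted gene PHLDA2 by 1.36 (SE 0.25), the nucleoside kinase NME2 by 1.26 (SE 0.21) and the GATA cofactor ZFPM1 by 1.30 (SE 0.18). The antiviral genes OAS2, IFI27, MX1, MX2 and ISG15 were lower, by -2.07 (SE 0.14), -2.06 (SE 0.15), -1.79 (SE 0.09, adjusted p = 4.93e-08), -1.67 (SE 0.16) and -1.54 (SE 0.09). In all, 858 genes were enriched and 602 lower of 13101, 38 and 53 by at least 2-fold. FTL differed by -0.06 (SE 0.09, adjusted p = 0.709).

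Also enriched were the histone H4C3 (1.67), GTF2IRD2B (1.40), MAGED4B (1.31) and LRRC26 (1.29). Lower were the snoRNAs SNORA25, -1.79, SNORA41, -1.71, and SNORA32, -1.64, the snoRNA host SNHG6, -1.56 (SE 0.12), and the splicing protein HNRNPA3, -1.53 (SE 0.24). H4C3 had an adjusted p of 0.0508 and 0.0719 without miR-638 pulldown replicate 1 or 2. The calls of the snoRNAs were lost without miR-638 pulldown replicate 1 (adjusted p = 0.0798 for SNORA25, 0.108 for SNORA41, 0.0616 for SNORA32), 2 (0.0876, 0.112 and 0.0746) or 3 (0.0526, 0.0887 and 0.0694). The 3 probes of GTF2IRD2B ran from -0.02 to 1.40 and those of NME2 from -0.07 to 1.26. Without miR-638 pulldown replicate 1, 2 or 3 the count of 1460 genes for miR-638 pulldown against both controls was 633, 541 and 654. It was 2507 with array weights and 839 with only the groups of the comparison. With the authors' values it was 100, 60 higher and 40 lower, and FTH1P3 was enriched by 1.44 (adjusted p = 0.0577). Against each control alone 495 genes passed in 1 direction, 347 enriched and 148 lower. With the replicate block 1518 passed, 1338 of them shared. Of all genes tested, 1949 had the 3 miR-638 arrays outside all 6 control arrays (14.9%, against 2.38% by chance).

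Interferon-stimulated genes were lower as a group in the miR-638 pulldown: 33 of 43 were lower, 0 higher and 10 not past (38 lower adjusted over the list alone; 33 with the replicate block). Their median was -0.80 (camera adjusted p = 5.02e-36; adjusted p = 2.26e-04 with an estimated correlation). The arrays named NC2 pulldown stood apart from all others in these genes, each at a median of 0.79 above the mean of the arrays, while those named NC1 lay between -0.15 and -0.06 and the miR-638 arrays between -0.46 and -0.45. Against NC1 alone the median was -0.32 (adjusted p = 3.54e-10), with MX1 at -0.97 and OAS2 at -0.98, and against NC2 alone it was -1.36.

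Immediate early genes were enriched in the miR-638 pulldown, 6 of 25, with 1 lower and 18 not past (8 and 1 adjusted over the list alone). Their median was 0.22 (adjusted p = 0.00104; 0.0493 with an estimated correlation; 0.0976 with the authors' values). CCN2 was enriched by 0.57 (SE 0.08), the transcription factor KLF2 by 0.76 (SE 0.12) and the AP-1 component FOSL1 by 0.48 (SE 0.08). Ribosomal proteins had 12 of 64 higher and 1 lower (14 and 1 adjusted over the list alone). Their median was 0.09 (adjusted p = 0.00103; adjusted p = 0.723 with an estimated correlation; with the authors' values the median was -0.00 and the adjusted p 0.542). Among them FAU rose by 1.18 (SE 0.07) and RPS6 by 0.68 (SE 0.07). The respiratory chain had 10 of 53 higher and 0 lower (12 and 2 adjusted over the list alone). The median was 0.06 (adjusted p = 0.0241; adjusted p = 0.749 with an estimated correlation). NDUFS8 rose by 0.95 (SE 0.08) and COX5A by 0.87 (SE 0.07). Histone genes had 6 of 29 higher and 0 lower (7 and 0 adjusted over the list alone), among them H1-2 by 0.48 (SE 0.08). Their median was 0.16 (adjusted p = 0.0269; adjusted p = 0.723 with an estimated correlation; 0.424 against NC2 alone). Without NC1 pulldown replicate 2 the respiratory and histone calls were lost (0.105 and 0.0709). So were the respiratory call without NC2 pulldown replicate 3 (0.0648) and the histone call without miR-638 pulldown replicate 2 (0.066). With the authors' values both were lost (0.324 and 0.377).

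The remaining lists did not pass camera in the miR-638 pulldown. In the iron list 5 of 26 genes were higher and 2 lower (5 and 4 adjusted over the list alone). The siderophore binder LCN2 differed by 1.18 (SE 0.16), the iron chaperone PCBP1 by 0.41 (SE 0.07), and the transferrin receptor TFRC by -0.44 (SE 0.07). Reported miR-17 targets had 2 of 45 higher and 9 lower (3 and 9 adjusted over the list alone), with ZNFX1 at -0.61 and ANKFY1 at -0.45 (camera adjusted p = 0.0733). Reported miR-638 targets had 0 higher and 1 lower of 9 (1 and 2; adjusted p = 0.313). Splicing factors had 1 of 29 higher and 3 lower (the same counts adjusted over the list alone), among them U2AF1, which recognizes the 3' splice site, by -1.46 (SE 0.07), and TRA2A by -1.19 (SE 0.17). The S phase list had 3 of 41 higher and 5 lower (6 and 11 adjusted over the list alone), with the thymidine kinase TK1 at 0.77 and the chromatin assembly factor CHAF1B at -0.41. Mitosis had 4 of 44 higher and 0 lower (3 and 0), with BIRC5 at 0.81 and UBE2C at 0.45, a median of -0.04 and a mean of 0.01. The counts higher and lower were 3 and 2 of 26 p53 targets (the same adjusted over the list alone), 4 and 0 of 29 apoptosis genes (4 and 1), 3 and 0 of 29 growth genes (3 and 1), 3 and 0 of 28 epithelial and mesenchymal genes (4 and 2; KRT8 at 0.63), and 2 and 2 of 30 hypoxia genes (2 and 2; PGK1 at -0.47). They were 0 and 3 of 28 cholesterol genes (0 and 3), 0 and 1 of 27 unfolded protein genes (0 and 0), and 2 and 2 of 26 NRF2 genes (3 and 6; AKR1B10 at -0.57). Lastly, they were 1 and 0 of 20 NF-kB genes (1 and 0; IL11 at 0.88, and 0.27 against NC2 alone) and 1 and 1 of 16 genes of the microRNA machinery (1 and 1). Of the markers of other cells, 0 of 3 luminal, 1 of 7 blood and 0 of 3 fibroblast genes passed (0, 2 and 0 at an unadjusted p under 0.05). CD68 was higher by 0.51 (adjusted p = 0.0144), and its 3 probes ran from -0.0018 to 0.51. It was not past the test without miR-638 pulldown replicate 1 (0.0531), 2 (0.0837) or 3 (0.0506), or against NC2 alone (0.118).

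The miR-17 pulldown, the bait with another seed, was compared in the same way. Enriched were the deubiquitinase USP12 by 2.42 (SE 0.11, n = 3 against 6, adjusted p = 8.55e-09), the single-strand DNA binder NABP1 by 2.16 (SE 0.07, adjusted p = 2.45e-10). The histone methyltransferase SUV39H1 was enriched by 1.87 (SE 0.09), the mitotic kinase PBK by 1.80 (SE 0.08), the calpain subunit CAPNS1 by 1.78 (SE 0.06) and the cofilin CFL2 by 1.81 (SE 0.15). The cell cycle inhibitors CDKN1B and CDKN1A were enriched by 1.76 (SE 0.11, adjusted p = 1.38e-07) and 0.77 (SE 0.09). FTH1P3 was enriched by 0.33 (SE 0.08, adjusted p = 0.0165), against 1.25 in the miR-638 pulldown. In all, 1084 genes were enriched and 790 lower, 87 and 97 by at least 2-fold. FTL differed by 0.09 (SE 0.09, adjusted p = 0.559).

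Other genes of largest enrichment were ZNF77 (2.22), CLPTM1 (2.05) and RASL11B (1.83). The hydroxylase FA2H was enriched at least 3.6-fold, a bound, since it was detected on 3 of 3 miR-17 arrays and 1 of 6 controls. The largest decreases were the ribosomal RNA gene RNA28SN5, -2.07 (SE 0.38), and EBLN2, -1.95. Next were SMCR5, -1.88, SNORA25, -1.81, MIR181A2HG, -1.69, IFI27, -1.61 (SE 0.15), TNFSF15, -1.58, SNORA32, -1.57, and LMOD3, -1.55. The linker protein DST, detected on 1 of 3 miR-17 arrays, was at least 3.85-fold lower, a bound, and its 5 probes reached 0.12. The 2 probes of TNFSF15 ran from -1.58 to 0.17. Against NC2 alone SMCR5 had an adjusted p of 0.0531 and TNFSF15 of 0.0719. Over all main comparisons, 48 calls of named genes were lost against NC2 alone and 30 against NC1 alone, and not all are given here. Calls were lost without miR-17 pulldown replicate 1 for EBLN2 (adjusted p = 0.096), SNORA25 (0.0551), MIR181A2HG (0.0715), TNFSF15 (0.0848), SNORA32 (0.0938) and LMOD3 (0.0758). They were lost without replicate 2 for EBLN2 (0.0883), SNORA25 (0.0528), MIR181A2HG (0.0645), SNORA32 (0.0537) and LMOD3 (0.0649). Without replicate 3 they were lost for EBLN2 (0.0572), SNORA25 (0.0615), MIR181A2HG (0.0628), TNFSF15 (0.0552) and LMOD3 (0.073). FTH1P3 had an adjusted p of 0.109 and 0.0645 without miR-17 pulldown replicate 2 or 3. It was 0.0962 against NC2 alone and 0.502 with the authors' values. Without miR-17 pulldown replicate 1, 2 or 3 the count of 1874 genes for miR-17 pulldown against both controls was 978, 1011 and 1019. With the authors' values it was 203, and with array weights 2860. In the blocked fit 1865 passed, 1750 of them shared. Of all genes, 736 passed against each control alone in 1 direction. Of all genes tested, 2188 had the miR-17 arrays outside all 6 control arrays (16.7%, against 2.38% by chance).

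Interferon-stimulated genes were lower in the miR-17 pulldown too, 31 of 43, with 1 higher and 11 not past (34 and 2 adjusted over the list alone). Their median was -0.70 (adjusted p = 4.35e-23; 6.25e-04 with an estimated correlation), with MX1 lower by -1.55 (SE 0.09) and PARP9 by -1.19 (SE 0.11). Against NC1 alone the median was -0.16 (adjusted p = 0.00702) and against NC2 alone -1.10. NF-kB and inflammatory genes were lower, 4 of 20, with 2 higher and 14 not past (8 and 2 adjusted over the list alone). Their median was -0.29 (adjusted p = 0.00908; adjusted p = 0.121 with an estimated correlation; 0.0728 against NC1 alone and 0.127 with the authors' values). CXCL8 differed by -1.03 (SE 0.16) and IL6 by -0.92 (SE 0.14), with CXCL1 higher by 0.82 (SE 0.14). Ribosomal proteins had 9 of 64 higher and 0 lower (10 and 0 adjusted over the list alone). Their median was 0.10 (adjusted p = 0.00304; adjusted p = 0.749 with an estimated correlation; 0.0829 against NC2 alone and 0.387 with the authors' values), with RPS24 at 0.44 and RPLP1 at 0.41.

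The other lists did not pass camera in the miR-17 pulldown. Reported miR-17 family targets went both ways, 8 of 45 higher and 7 lower (9 and 8 adjusted over the list alone), with a median of -0.05, a mean of 0.05 and an adjusted p of 0.986. The higher ones included TXNIP, an inhibitor of thioredoxin, by 1.22 (SE 0.12), MICA, a ligand of natural killer cells, by 0.99 (SE 0.10), and CDKN1A. Growth and invasion genes had 5 of 29 higher and 4 lower (7 and 6), with CDKN1B at 1.76 and CDK6 at 0.98. In the cholesterol list 2 of 28 were higher and 1 lower (the same adjusted over the list alone), with MSMO1, a sterol oxidase, at 1.44 (SE 0.08; list adjusted p = 0.0908). In the iron list 3 of 26 were higher and 1 lower (also adjusted over the list alone), with the ferric reductase CYBRD1 at -1.43 (SE 0.09). The respiratory chain had 7 of 53 higher and 1 lower (also adjusted over the list alone; COX5B at 1.07 and COX4I1 at 0.49), and mitosis 9 of 44 and 2 (10 and 2; CCNB1 at 0.70). In the same order the counts were, for hypoxia, 3 of 30 and 7 (3 and 9; EGLN3 at 0.89 and CA12 at -0.60), NRF2 genes 5 of 26 and 1 (7 and 2; AKR1B10 at 0.89 and SOD1 at 0.50), and the microRNA machinery 1 of 16 and 1 (1 and 2; AGO1 at -0.98, SE 0.09). The counts were 3 and 7 of 41 S phase genes (4 and 9; MCM10 at -0.39), 5 and 3 of 26 p53 targets (5 and 3; TNFRSF10B at -0.58), and 3 and 5 of 29 apoptosis genes (4 and 7). They were 1 and 1 of 28 epithelial and mesenchymal genes (1 and 0; KRT8 at 0.53), 1 and 2 of 27 unfolded protein genes (1 and 2; VLDLR at -0.66), and 1 and 0 of 29 histone genes (1 and 0; H3C2 at 0.87). They were 3 and 0 of 29 splicing factors (3 and 0; U2AF1 at 0.55), 1 and 3 of 25 immediate early genes (1 and 3; DUSP6 at -0.55) and 0 and 1 of 9 reported miR-638 targets (0 and 1). Among markers of other cells 0 of 3 luminal, 0 of 7 blood and 0 of 3 fibroblast genes passed limma's test (3, 2 and 1 unadjusted; 1 higher and 2 lower luminal genes adjusted over the list alone), with LYZ, detected on 3 of 6 control arrays, at least 1.39-fold higher (adjusted p = 0.0567).

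Between the baits, FTH1P3 was higher with miR-638 than with miR-17 by 0.92 (SE 0.09, n = 3 against 3, adjusted p = 2.5e-05), and CTSZ by 1.47 (SE 0.20, adjusted p = 2.87e-04). SLC25A23, lowered by the miR-638 mimic, was lower with miR-638 than with miR-17 by -2.70 (SE 0.12, adjusted p = 1.4e-08), ZNF77 by -2.58 (SE 0.14) and NABP1 by -2.42 (SE 0.08). RNA28SN5 (1.91) and H4C3 (1.51) were also higher with miR-638. RNA28SN5 had an adjusted p of 0.0625 without miR-638 pulldown replicate 2 and 0.0827 without miR-17 pulldown replicate 1. H4C3 had an adjusted p of 0.0521 without NC2 pulldown replicate 3, of 0.116, 0.152 and 0.0739 without miR-638 pulldown replicate 1, 2 or 3, and of 0.0719, 0.105 and 0.164 without miR-17 pulldown replicate 1, 2 or 3. In miR-638 pulldown against miR-17 pulldown 431 genes were higher and 673 lower. Without miR-638 pulldown replicate 1, 2 or 3 these 1104 were 634, 623 and 698. Without miR-17 pulldown replicate 1, 2 or 3 they were 646, 666 and 693, and with the authors' values they were 132. They rose to 2441 with array weights, 2635 with only the groups of the comparison and 2268 without the control arrays numbered 2, an alternative chosen after seeing the data. In the blocked fit 1022 passed. The arrays of the baits did not overlap in 4530 of all genes tested (34.6%, against 10% by chance).

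In NC2 pulldown against NC1 pulldown, the antiviral genes OAS2 and IFI27 and the glycosyltransferase GALNT1 were higher in the arrays named NC2, by 2.17 (SE 0.16, n = 3 against 3, adjusted p = 7.41e-06), 1.99 (SE 0.17) and 1.96 (SE 0.12). The DNA repair nuclease DCLRE1C was lower by -1.44 (SE 0.19), IQCN by -1.35 (SE 0.14) and the homeobox gene HOXC8 by -1.16 (SE 0.12). These names are those of the signal table. The authors' value table has the opposite signs for IFI27 (-2.21), GALNT1 (-1.60), DCLRE1C (1.91), IQCN (1.24) and HOXC8 (1.26). OAS2 reversed neither with its columns as named nor with them exchanged, so it gave no direction there. In all, 401 genes were higher and 213 lower, 51 and 5 by at least 2-fold. The 614 were 369 without NC1 pulldown replicate 1, 315 without NC2 pulldown replicate 3, 101 with only the groups of the comparison and 4 with the authors' values. In the blocked fit 579 passed. The arrays did not overlap in 2608 of all genes tested (19.9%, against 10% by chance).

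**Figure D3:**
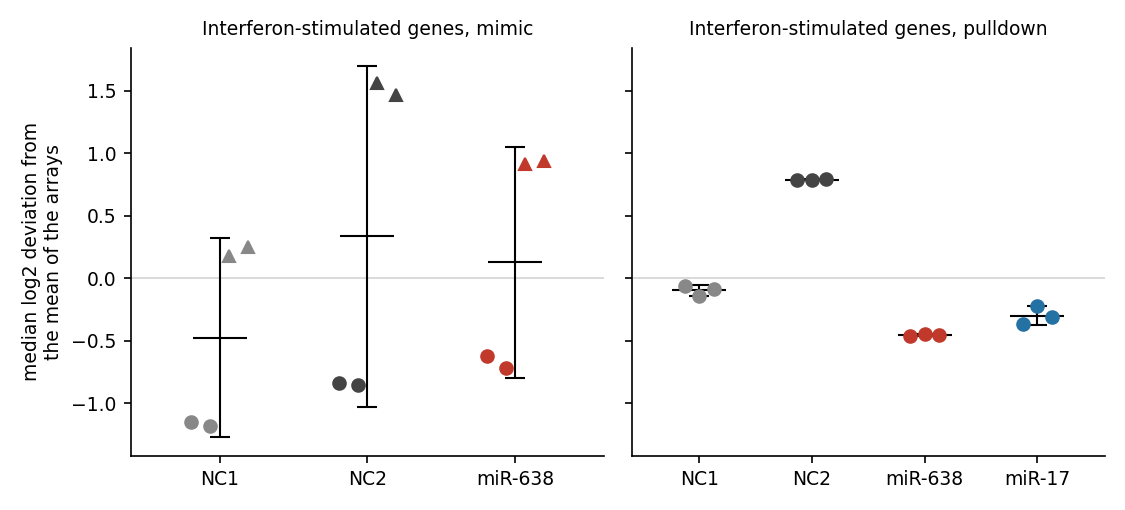
Median over the interferon-stimulated genes of the log2 deviation from the mean of the experiment's arrays, for each array (circles, mimic replicates 1 and 2 and all pulldown arrays; triangles, mimic replicates 3 and 4), with the mean and SD of each group. The mimic arrays part by replicate pair, and the arrays named NC2 pulldown lie at 0.79.

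Transcripts enriched in the miR-638 pulldown were then followed in the mimic experiment. Genes are not independent replicates, so the p-values and intervals of Fisher's exact test do not measure the spread between arrays. Of the 38 genes enriched at least 2-fold, 6 fell after the miR-638 mimic (15.8%, against 1.33% of other genes; odds ratio 13.9, 95% interval 4.68 to 34.3, Fisher's exact p = 1.2e-05, adjusted p = 4.2e-05 over 14 tests) and 0 rose. They were RTL8C (enriched by 1.73, -1.28 after the mimic), LDOC1 (1.44, -0.79), FTH1P3 (1.25, -1.17), NME2 (1.26, -0.35), TMEM114 (1.17, -0.89) and ARL2BP (1.09, -0.32). The 38 genes had a mean of -0.09 and a median of -0.04 in the mimic experiment, and 23 lay below 0. The shift of the mean did not pass (camera p = 0.0308, adjusted p = 0.0864; p = 0.0668 with an estimated correlation; p = 0.0768 with the replicate block). With quantile normalization only, 64 genes were enriched and their mean turned to 0.041, while 8 of the 61 measured after the mimic fell (odds ratio 11.1, Fisher's exact p = 1.9e-06). With the replicate block in both experiments, the enriched genes lower after the mimic were 9 of 38 (odds ratio 3.03, Fisher's exact p = 0.00703). Of the 25 also above the miR-17 pulldown, 6 fell (odds ratio 23.4, Fisher's exact p = 8.93e-07). Of 86 genes enriched at least 2-fold with miR-17, 3 fell after the miR-638 mimic (odds ratio 2.62, Fisher's exact p = 0.115). Of the 38, 1 was lower in NC2 than in NC1 mimic cells (odds ratio 0.505, Fisher's exact p = 1).

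Of these, RTL8C and LDOC1 kept their mimic call without any 1 array. FTH1P3 lost it as given above, and TMEM114 without miR-638 mimic replicate 1 (adjusted p = 0.0878) or 2 (0.058). NME2 (adjusted p = 0.0495 after the mimic) lost it without any 1 of the 12 mimic arrays, at an adjusted p up to 0.181 without miR-638 mimic replicate 2, and ARL2BP (0.0388) without any 1 but NC2 mimic replicates 1 and 2 and miR-638 mimic replicate 4, up to 0.148 without miR-638 mimic replicate 2. The number of enriched genes that fell was between 2, without miR-638 mimic replicate 1, and 9, without NC2 pulldown replicate 1. Without the size threshold the 848 enriched genes leaned the other way, with a mean of 0.06 (camera adjusted p = 0.0853, not past). Of them 28 fell (odds ratio 2.73, Fisher's exact p = 1.79e-05) and 60 rose (odds ratio 4.50, Fisher's exact p = 4.74e-18). This overlap was not particular to miR-638. Of the 1074 genes enriched with miR-17 at any size, 26 fell (odds ratio 1.92, Fisher's exact p = 0.00548) and 58 rose (odds ratio 3.27, Fisher's exact p = 2.95e-12) after the miR-638 mimic. Of the 848, 91 were lower in NC2 than in NC1 mimic cells (odds ratio 2.46, Fisher's exact p = 5.47e-12). Across 12265 genes, which are not independent replicates, the mimic and miR-638 pulldown differences correlated at r = 0.124 and rho = 0.125. The differences between the NC2 and NC1 mimics correlated with the same pulldown at r = -0.178, and 158 of 214 genes that differed in both had opposite signs.

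**Figure D4:**
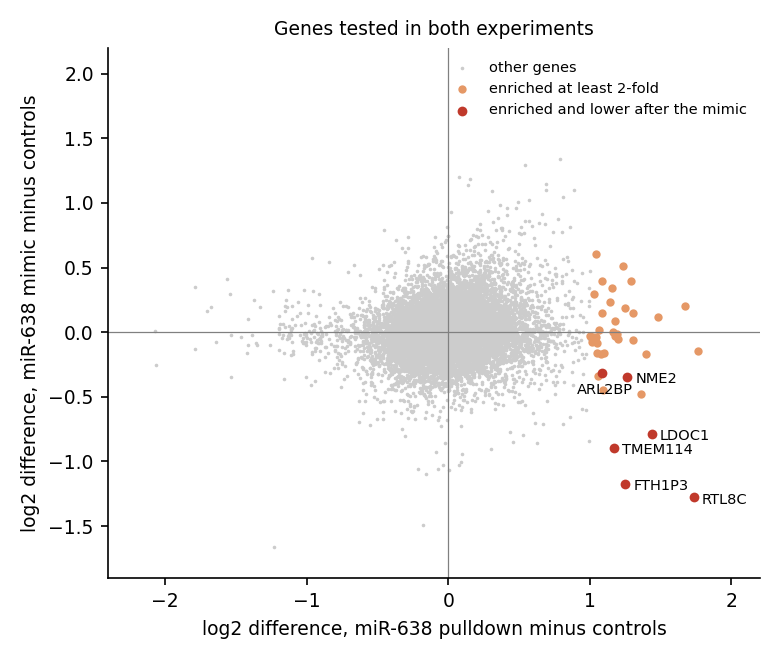
Log2 difference after the miR-638 mimic (vertical) against log2 difference in the miR-638 pulldown (horizontal) for each gene tested in both experiments. Of the 38 genes enriched at least 2-fold, 6 fell after the mimic and are named.

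The pulldowns shared more genes than separate draws would give. In both, 271 genes were enriched, where 71.0 would be by independent draws, and 228 were lower, where 36.3 would be; 42 went opposite ways and 7 were enriched at least 2-fold in both. The interferon-stimulated genes MX1 and IFI27 were lower in both, and the mitotic survivin gene BIRC5, the oxidase subunit COX5A and the keratin KRT8 higher. Across genes, which are not independent replicates, the differences correlated at r = 0.54, with a covariance of 0.0504. In 100 simulations of unchanged groups set against shared controls these were 0.33 and 0.00756. The simulated groups held no changed genes, so their 0 genes shared in either direction follow from that. They give no expected overlap for changed groups with shared controls. The simulated controls did not differ from each other either, while the real control pulldowns differed in 614 genes. A change in either control alone moves both differences the same way. The gap in r and covariance therefore does not show agreement beyond the shared controls. With split controls, each bait against another control, 159 and 141 genes were enriched in both (55.9 and 51.3 by independent draws). Lower in both were 67 and 57 (27.3 and 26.5 by independent draws). More, 76 and 70, went opposite ways, and r was 0.29 and 0.26. The 271 genes higher in both were 136, 149 and 137 without miR-638 pulldown replicate 2, 1 or 3, 153, 149 and 155 without miR-17 pulldown replicate 1, 2 or 3. They were 410 without NC2 pulldown replicate 1, 152 with only the groups of the comparison, 492 with array weights and 10 with the authors' values.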

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

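Of the tests in this part, the one on the covariance of the NC2 oligonucleotide was written before its result was seen. The others were set up after theirs were seen. The fits against NC1 alone and with other scalings were planned as alternatives, but their reading here was chosen afterwards.

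TP53INP1 lay at 8.28 (log2) on NC1 mimic replicate 4, against 8.58 to 8.60 on the other 3 arrays of its group. AGO3 lay at 6.30 on NC2 mimic replicate 1, against 6.47 to 6.50. STRADB lay at 7.69 on NC2 mimic replicate 1, against 7.99 to 8.02. These are 3 of 213 groups examined, and chance gives a distant array in about 1 in 20 groups. Among probes with no gene name, which the comparisons do not use, 26 were enriched at least 2-fold in the miR-638 pulldown, of which 11 were lower after the miR-638 mimic and 14 lay below 0; ILMN_3275771 was enriched by 1.34 and lay at -1.15 after the mimic, and ILMN_2134538 by 1.24 and at -1.21 (both chosen after their values were seen).

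The 6 control pulldown columns are exchanged between the signal table and the authors' value table: they correlate at 0.005 to 0.36 with the column of their own name and at 0.60 to 0.85 with the exchanged one, while the other 18 match their own. An exchange in the signal table needs the 269 genes moved by the NC2 mimic alone to set the arrays named NC1 pulldown apart from the other groups by more than those named NC2, and the 121 genes moved by the NC1 mimic alone to do the reverse; the differences were 0.164 and 0.116, and -0.164 and -0.116 for an exchange in the authors' table. They lie under the largest SD between arrays of any group, 0.186, by which the explanations cannot be told apart, but above that of the compared groups alone, 0.0602, a narrower spread tried after that verdict was seen, by which an exchange in the signal table would fit. Interferon-stimulated genes leaned as the signal table names them, at a median of 0.67 with the NC2 mimic (0 of 42 past limma's test, 1 unadjusted, 31 in the blocked fit; camera p-values of 6.79e-04 at the preset and 0.527 at the estimated correlation) and at 0.79 in the arrays named NC2 pulldown against -0.15 to -0.06 in those named NC1, and a bait may also enrich its own targets, which turns the reading round (GALNT1 was lower with the NC2 mimic by -2.25 and higher in the arrays named NC2 pulldown by 1.96). The correlation estimated for these genes in the mimic experiment, 0.895, came from a fit with no term for the pairs of replicates. It therefore includes the shift between those pairs. No biological explanation was tested.

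More genes differed between the NC2 and NC1 mimics, 1275, than between miR-638 and both controls, 422. The shift between replicates 1 and 2 and replicates 3 and 4 is argued against as the whole cause, since within these pairs the ratio of the counts was 1.57 and 2.54. The scaling of the arrays is argued against too, with ratios of 2.69 to 3.4 over 4 other scalings. Changes specific to the NC2 oligonucleotide are a candidate explanation: the differences of NC2 from one group in replicates 1 and 2 and from the other in 3 and 4 had a covariance over genes of 0.0486 and 0.0498, against 0.0269 and 0.0256 for NC1 and 0.0110 and 0.00970 for miR-638. This was found and tested on the same arrays, and remains a hypothesis.

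Interferon-stimulated genes were lower in both microRNA pulldowns than in the controls. Outlying control arrays numbered 2 are argued against, as without them the medians were -0.865 and -0.73 for miR-638 and miR-17. A high level in the arrays named NC2 pulldown alone is argued against as the whole cause, since against the arrays named NC1 alone the medians were -0.321 and -0.159; most of the difference went with the NC2 arrays all the same. A different interferon response of the transfected cells stays open, since the cells used for the pulldown were not measured before it. After the miR-638 mimic the list did not pass camera, at a median of 0.0694 (adjusted p = 0.819) and of -0.06 in replicates 3 and 4. It passed as higher in replicates 1 and 2 (0.17, adjusted p = 7.24e-04) and against NC1 alone (0.44, adjusted p = 0.0402). These rises are opposite to the fall in the miR-638 pulldown, and so give this explanation no support.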

How the results depend on the processing

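The alternatives named with replicates 1 and 2 or 3 and 4, the batch term, the control arrays numbered 2, the exchanged columns and both controls at once were chosen after seeing the data. Over the alternatives other than leaving out 1 array in turn, named genes kept direction and side of the threshold in 3379 cases, lost the call in 333, gained one in 61 and reversed in 11. List tests did so in 910, 34, 16 and 0. For the named genes, the authors' values alone account for 146 of the lost calls and 9 of the reversals. Only 114 cases stayed the same under them. Signal over background limits genes near the detection floor, at a log2 level of 4.83 to 4.96 in the mimic experiment and 5.01 to 5.15 in the pulldown. Seed-site alternatives were not run. Except where fewer arrays or probes account for a change by construction, the cause was not tested. Numbers in brackets after a gene are adjusted p-values, and those after the mean log2 difference of enriched genes are limma's unadjusted camera p-values. The latter was 0.0308 in the report, and did not pass when adjusted (adjusted p = 0.0864).

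With quantile normalization only, 64 genes were enriched at least 2-fold with miR-638, and the mean log2 difference of enriched genes was 0.041 (0.14; reversed). With the authors' values 100 genes differed in miR-638 pulldown against both controls, 203 in miR-17 pulldown against both controls, 132 in miR-638 pulldown against miR-17 pulldown and 4 in NC2 pulldown against NC1 pulldown (4 with the columns exchanged). FTH1P3 was -1.18 (0.0609) after the mimic, 1.44 (0.0577) in the miR-638 and 0.45 (0.502) in the miR-17 pulldown. After the mimic 1 list passed, in the miR-638 pulldown 2 and in the miR-17 pulldown 1. There were 10 genes higher in both, and the mean was -0.027 (0.177). Reversed with the authors' values were MCM3 (0.048), VEGFA (0.11) and SOD1 (-0.097) in the miR-638 pulldown and SOD1 (-0.0032) in the miR-17 pulldown, all given as log2 differences. Between the control pulldowns IFI27 (-2.21), GALNT1 (-1.60), DCLRE1C (1.91), IQCN (1.24) and HOXC8 (1.26) reversed, where the exchanged columns account for it. With no detection filter 6 lists passed in the miR-17 pulldown. With every detected probe, 73 and 142 were enriched at least 2-fold with miR-638 and miR-17. With no variance trend the mean was -0.088 (0.0635).

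With array weights 2507 genes differed in miR-638 pulldown against both controls, 2860 in miR-17 pulldown against both controls and 2441 in miR-638 pulldown against miR-17 pulldown, with 492 genes higher in both. Then 1 list passed after the mimic and 3 in the miR-638 pulldown, and the mean log2 difference of enriched genes was -0.07 (0.0505). With the replicate block 2432 genes differed in miR-638 mimic against both controls and 4164 in NC2 mimic against NC1 mimic, FTL was -0.21 (0.0272), 1 mimic list passed, and the mean was -0.095 (0.0768). With the batch term these were 2529, 4209, -0.21 (0.0216), 1 and -0.095 (0.0557). In replicates 1 and 2 they were 2316 and 3626, with FTL at -0.39 (2.84e-04). In replicates 3 and 4 they were 858 and 2176, with 0 mimic lists and a mean of -0.054 (0.0773).

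Against NC1 only, 1 mimic list passed, and FECH after the mimic (-0.0080) and JUND in the miR-17 pulldown (0.054) reversed. Against NC2 only, 871 genes differed in miR-638 mimic against both controls and FTH1P3 was 0.26 (0.0962) in the miR-17 pulldown. Past both controls at once were 94 genes after the mimic, 495 in miR-638 pulldown against both controls and 736 in miR-17 pulldown against both controls. With only the groups of the comparison 839 differed in the miR-638 pulldown, 2635 in miR-638 pulldown against miR-17 pulldown and 101 in NC2 pulldown against NC1 pulldown. The 152 genes higher in both and a mean log2 difference of enriched genes of -0.088 (0.0664) belong to this setting. Without the control pulldown arrays numbered 2, 24 genes were enriched at least 2-fold with miR-638, 2268 differed between the baits and 3 lists passed in the miR-638 pulldown. With no size threshold the mean was 0.064 (0.0183; reversed), with an estimated correlation -0.095 (0.0668), and with split controls 159 and 141 were higher in both pulldowns.

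With 1 array left out the counts ran from 162 to 358 after the mimic, 801 to 1238 between the control mimics, 541 to 1894 in the miR-638 pulldown (27 to 52 enriched at least 2-fold) and 978 to 2163 in the miR-17 pulldown (78 to 98). They ran from 623 to 1569 between the baits, 315 to 908 between the control pulldowns and 136 to 410 for genes higher in both. Lists past the test numbered 1 to 4, 3 to 6 and 3 to 4 after the mimic and in the miR-638 and miR-17 pulldowns. FTH1P3 ran from -1.40 to -0.94, 1.21 to 1.28 and 0.26 to 0.40 in these, and FTL from -0.35 to -0.09, -0.11 to -0.01 and 0.04 to 0.15. Of the enriched genes 2 to 9 were lower after the mimic. Leaving out 1 mimic array also unbalances the pairs of mimic replicates, whose shift then enters the fit. The mean log2 difference of enriched genes ran from -0.14 to -0.047. Its unadjusted p was over 0.05 (0.0529 to 0.163) without NC1 mimic replicate 4, NC2 mimic replicate 4, miR-638 pulldown replicate 1 or 3, or any miR-17 pulldown array.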

Other observations

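In this part the counts over other splits were planned, and all other genes and contrasts were chosen after their values were seen.

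The pairs of mimic replicates differed in more genes than any treatment, 7253 (3326 higher and 3927 lower in replicates 3 and 4, 345 and 117 by at least 2-fold). The 6 arrays of a side all belong to the same pair of replicates. The SEs and adjusted p-values here therefore measure the spread within the pairs, not between them. Interferon-stimulated genes were higher in replicates 3 and 4 as a group, 41 of 42, at a median of 1.99 (camera adjusted p = 7.40e-35; 0.0175 with an estimated correlation): IFITM3, which blocks viral entry, by 4.41 (SE 0.06, n = 6 against 6), OAS2 by 4.22 (SE 0.10) and MX1 by 3.46 (SE 0.06). The Wnt-responsive genes AXIN2 and LEF1 were lower by -4.64 (SE 0.07) and -3.62 (SE 0.09). Cholesterol and fatty acid synthesis had 17 of 28 lower and 3 higher, at a median of -0.40 (adjusted p = 1.52e-04; adjusted p = 0.0774 with an estimated correlation), splicing factors 21 of 29 lower and 1 higher, at -0.19 (0.00152; 0.0644 with an estimated correlation), and unfolded protein genes 15 of 27 lower and 2 higher (0.0114; 0.346). Epithelial and mesenchymal genes had 14 of 26 higher and 3 lower (0.00299; 0.0644), and hypoxia genes 16 of 31 and 4 (0.00929; 0.137).

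Treatment effects also differed between the pairs, against the same spread within pairs. The effect of miR-638 differed in 64 genes (26 and 38), among them FTH1P3 by 1.04 and RTL8C by 1.01. The effect of NC2 against NC1 differed in 120, and interferon-stimulated genes rose with NC2 by a median of 1.00 more in replicates 3 and 4, 27 of 42 past the test (camera adjusted p = 9.98e-76; 0.00198 with an estimated correlation), with IFI27 at 2.54. By the names of the signal table, the controls differed in opposite directions in the experiments: of 185 genes that differed between NC2 and NC1 in both, 165 had opposite signs, 118 of them lower after the NC2 mimic and higher in the arrays named NC2 pulldown. GALNT1 lay at -2.25 and 1.96, the phosphatase PPP1CC at -1.24 and 1.08 and the mTORC1 scaffold LAMTOR3 at -1.41 and 1.06. Across 12265 genes, which are not independent replicates, r was -0.203. The names of the control pulldown columns are open: with these exchanged, the same 165 genes would share a sign and r would be positive. For miR-638, 112 genes differed in both experiments, 80 of them in the same direction and 32 in opposite directions.

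Labels were exchanged over other splits of the same arrays, which treats the arrays as independent. Replicates may be technical, so these shares do not exclude chance differences between cultures. For the miR-638 mimic 2 of 100 splits, the real one included, gave as many as the real 422 genes. The highest other gave 2194 and follows the pairs of replicates, which points to that structure. With labels exchanged within replicate numbers and the replicate block it was 1 of 100, the real 2432 against 551. For the miR-638 pulldown it was 1 of 100, 1460 against 759. That other split kept the miR-638 arrays together and exchanged only control names. Its differences from the mean of both controls are therefore the real ones, with another spread. For the miR-17 pulldown it was 1 of 100, 1874 against 99. For NC2 against NC1 mimic the share was not under 0.05 (2 of 35, 1275 against 2718). The larger split is that of replicates 1 and 2 from 3 and 4. With the replicate block 4164 genes passed, and 3626 and 2176 within the pairs. For miR-638 against miR-17 (1 of 10; 1104 against 0 by limma) and for the control pulldowns (1 of 10; 614 against 1) the splits are too few for a share under 0.05.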
